A study of Mus musculus with 3 samples.

How the data were processed

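RNA was measured in 3 tumor nodules from 1 mouse of the RP model of small cell lung cancer (SCLC), in which floxed alleles of Rb1 and Trp53 are deleted in lung cells by an adenovirus that carries Cre recombinase under a CMV promoter. The tumors arose within 8 months after the virus. There were 2 nodules from the lung (primary lung tumor, replicates 1 and 2) and 1 nodule from the liver (liver metastasis). Per the labels' protocols, cDNA was made with an oligo-dT based SMARTer kit and sequenced as paired ends on an Illumina NovaSeq instrument. A kit of this kind does not mark the strand, so reads of a gene and of an overlapping or antisense neighbor cannot be told apart.

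The authors deposited 1 table of 27104 genes with whole-number counts and FPKM values for each library, per the file headers. FPKM values are fragment counts scaled by gene length and library size, computed by the authors; the gene length they used is not given in the sources used here. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR without saying what each was used for, and the counting step, annotation and genome build are not given in the sources used here. Of the 27104 gene identifiers, 27044 were also in GENCODE M21, an annotation of the GRCm38 mouse build, and 24277 of these had the same chromosome, start and end there; coordinates are printed as the table gives them. A gene symbol stood on more than 1 row in 41 cases; the row with the most counts kept the bare symbol. No column of per-sample values was left without a sample.

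The deposited counts summed to 46403899 in lung tumor 1, 47900533 in lung tumor 2 and 51702995 in the liver metastasis. Mitochondrial genes took 1.90%, 1.88% and 3.17% of the counts. A count of 0 was given a floor of 3 counts per library, which corresponds to 0.062, 0.0574 and 0.066 CPM (counts scaled to a common library size) in lung tumor 1, lung tumor 2 and the liver metastasis. Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only. The lung libraries were checked for being the same library: the chi-square of their counts was 72.3 times its degrees of freedom over 20125 genes with a summed count of at least 20.

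The main comparison was the liver metastasis against the lung tumors with edgeR 4.0.16 in R 4.3.3: filterByExpr kept 21965 genes, libraries were scaled by TMM (factors 1.043, 1.091 and 0.879), and the quasi-likelihood test (glmQLFit, glmQLFTest) was adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05. The spread came from the lung nodules alone, which leaves 1 residual degree of freedom per gene before information is shared across genes (8.59 prior degrees of freedom), and the lone liver library was assumed to vary like them. All nodules came from 1 mouse, so edgeR p-values measure the spread between these nodules and not between mice. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic, an approximation. Folds between groups are ratios of TMM-scaled CPM; for a gene at 0 in every library of a group the fold is a lower bound against the floor, and its fitted fold change is not given.

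Because the liver group holds 1 library, a rule of size was set beside the test: the liver value at least 4-fold above or below the nearer lung library after adding 1 CPM, with a mean of at least 5 CPM. The same count with each lung library taken as the odd one out gave its background. edgeR was also run on those splits, but there the liver library shares a group with a lung library, so the difference between the sites enters the spread, and its counts are not used as a background. The lung tumors were compared with each other by the same 4-fold limit, with no test.

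The 33 gene lists cover tumor subtypes, cell types a nodule could hold, pathways and handling of the tissue. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Beside it stood camera with an estimated correlation, fry, and the percentile of the list's median among 10000 random lists matched on expression in 20 bins. With a preset correlation, camera p-values rest on the spread across genes, and not across nodules or mice. Counts of members are given from the test over all genes and adjusted over the list alone. Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

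Genes were named by this rule: single genes fixed beforehand, among them Rb1, Trp53, Neurod1, Pou2f3, Yap1, Mycl, Mycn, Myc and Nfib, always; up to 12 genes per direction that passed the test and the rule of size, by their fold to the nearer lung library; the 5 largest folds each way between the lung tumors; and for each list the 2 members with the highest mean and the 2 with the largest fold change. Predicted genes, pseudogene-like copies, immunoglobulin and T cell receptor segments, and Y-linked genes or Xist were left out of the parts on size and on the lung tumors. The rule gave 153 genes, of which those that matter for each group are named; some results for single genes are not reported. Other members of short lists of calls, and Alb, were named after their values were seen.

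The tests were checked on simulated counts for the real genes and library sizes. For the liver metastasis against the lung tumors, 7 of 100 genes changed by 2-fold and 86 of 100 changed by 8-fold were recovered among 20611 genes, and 11 of 104 calls were false. A planted gene list was recovered with a camera adjusted p of 5.25e-08, and 0 of 30 unchanged lists were called. The simulated genes varied independently of each other, so this does not show how often lists of correlated genes are called falsely. In a scan of 10274 genes for neighboring genes that shift together, a planted run of 40 genes was found.

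Alternatives were DESeq2 1.42.0, limma voom, an edgeR test against a 2-fold change, other scalings (DESeq2 size factors, upper quartile, library totals, TMM without hepatocyte, alveolar and erythroid genes), other filters (none, a mean count of at least 10), limma-trend on log2(FPKM + 1) of genes with a mean FPKM of at least 1 and with a pseudocount of 0.1 or no filter, predicted genes left out, and each lung tumor left out. The rule of size was also tried with 2-fold and 8-fold limits, with means of at least 1 and 20 CPM and on FPKM values, and the lists without hepatocyte genes in the background. A fit without mitochondrial genes was added after seeing the data. Python 3.11.15 with numpy, pandas, scipy and matplotlib served for the scan, its tests and the figures. The KEGG pathways that the deposited table lists for each gene were tested with camera as well, which was also decided after seeing the data.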

Results

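Gene expression was measured by RNA-seq in 2 primary lung tumor nodules and 1 liver metastasis nodule of the same RP mouse, a model in which loss of Rb1 and Trp53 in lung cells gives rise to small cell lung cancer. The libraries held 46403899 counts (lung tumor 1), 47900533 counts (lung tumor 2) and 51702995 counts (liver metastasis), and 22975, 22680 and 22887 genes had at least 1 count. The gene with the most counts was Calca in both lung tumors and Ubb in the liver metastasis. With 1 liver library and 1 mouse, a difference between the groups was set against the spread between the 2 lung nodules, and no replicate of the metastasis was at hand.

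The deleted genes and single regulators known from SCLC were read in each library first. Rb1 (ENSMUSG00000022105, chromosome 14, 73183673 to 73325822) stood at 3.12 and 2.28 CPM in lung tumors 1 and 2 and at 6.49 CPM in the liver metastasis, and did not pass the test (edgeR adjusted p = 0.153). Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) stood at 4.86 and 34.3 CPM in the lung tumors and at 13.5 CPM in the metastasis (edgeR adjusted p = 0.765); without lung tumor 2 it was higher in the metastasis, by 1.47 on the log2 scale. Gene-level counts include exons outside any floxed part and RNA of other cells, so these values check the deletions only in part. Neurod1, a neurogenic transcription factor, had 0 counts in both lung tumors and 75 counts in the metastasis, 1.65 CPM, which is at least 26.6-fold higher (edgeR adjusted p = 0.0396); the call ended with limma voom (adjusted p = 0.29), and its adjusted p over the tests run ranged from 0.00903 to 0.29. Yap1 was low throughout, at 1.32, 3.18 and 1.25 CPM, and Pou2f3 was not listed.

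Mycl (ENSMUSG00000028654, chromosome 4, 122995652 to 123002485), a MYC family oncogene often active in SCLC, rose from 95.9 ± 24.97 CPM (SD, n = 2) in the lung tumors to 382 CPM in the metastasis, a 3.99-fold difference (log2 fold change 1.995, SE 0.27, edgeR adjusted p = 0.00154). Myc fell, from 30.3 and 67.3 CPM to 14.7 CPM (log2 fold change -1.73, SE 0.46, edgeR adjusted p = 0.0402), and its call ended with limma voom (adjusted p = 0.239), and its adjusted p over the tests run ranged from 0.00139 to 0.396; without lung tumor 2 its log2 difference was -1.04. Mycn, at 11.5 and 9.05 CPM against 6.08 CPM, and Nfib, at 53.2 and 45.8 CPM against 49.9 CPM, did not pass the test; the sign of the Nfib difference turned with library totals (-0.26) and without lung tumor 2 (-0.09).

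The question of the main comparison was how the metastasis differed from the primary tumors. Genes of lung epithelium, stroma, antigen presentation and interferon response were lower in the metastasis, and genes of secreted plasma proteins, Spp1, neurofilaments and some mitotic genes were higher. Of 21965 genes tested, 2372 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (10.8%): 891 were higher and 1481 lower in the metastasis. By the rule of size, 82 genes lay at least 4-fold above and 381 at least 4-fold below the nearer lung tumor, and all of them also passed the test. With lung tumor 1 as the odd one out the rule gave 4 genes above and 11 below, and with lung tumor 2 it gave 14 and 18. These counts may be too low, since the liver library is among the others there. Set directly against each other, lung tumor 1 lay at least 4-fold above lung tumor 2 for 19 genes and below for 29.

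The number of calls and their split depended on the tool and the scaling. limma voom called 277 genes, all among the 2372, with 143 higher and 134 lower (48.4% lower), the edgeR test against a 2-fold change called 961 (79.4% lower), and limma-trend on unfiltered FPKM called 0, with 5261 at an unadjusted p under 0.05. Scaling by library totals lowered the median log2 fold change of all genes from -0.07 to -0.35, and 79.6% of its 2603 calls were lower in the metastasis against 62.4% of the main calls. Leaving out lung tumor 1 raised the count above by size from 82 to 176, and leaving out lung tumor 2 gave 121.

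**Figure D1:**
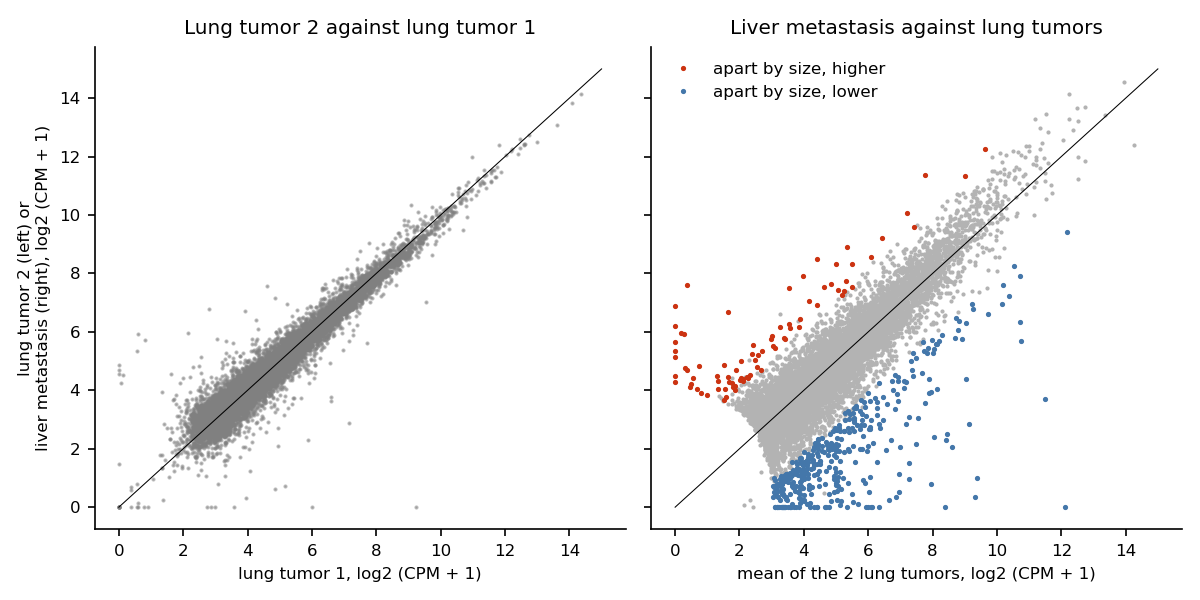
Each point is a gene with a mean of at least 5 CPM over the libraries, on log2(CPM + 1) axes with the line of equal values; the left panel sets lung tumor 2 against lung tumor 1 and the right panel the liver metastasis against the mean of the lung tumors. The 82 genes apart by size above the lung tumors are red and the 381 below are blue, and the cloud is wider on the right (SD of the log2 difference 0.98) than on the left (0.46).

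Several secretory neuroendocrine genes were lower in the metastasis, while the neuroendocrine list did not shift and some neuronal genes were higher. Calca (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357), which encodes calcitonin and CGRP, fell 3.63-fold from 19484 ± 2170 CPM (SD, n = 2) to 5367 CPM (log2 fold change -1.86, SE 0.22, edgeR adjusted p = 0.000812). Resp18 and the granule protein gene Chgb fell 5.97-fold and 5.88-fold. Of 22 neuroendocrine genes, 2 rose (Stmn2 and Sez6), 7 fell and 13 did not pass; adjusted over the list alone, 3 rose and 7 fell. The list did not shift against other genes (camera adjusted p = 0.843); its median was 0.20 and its mean -0.25, and the median was -0.08 with library totals. Neuronal genes of the Neurod1-associated list were higher (camera adjusted p = 0.0137, and 0.618 with an estimated correlation; median log2 fold change 0.89). Of its 15 tested members, 4 rose: Neurod1, the neurofilament genes Nefl (log2 fold change 1.77) and Nefm (2.099), and Rbfox3 (1.86). Neurod4 and Gap43 fell, and Elavl3, at 57.9 and 72.5 CPM against 121 CPM, passed over the list alone, which made 5 risen and 2 fallen there. The median of the neuronal list on the log2 CPM scale went from 0.896 to 0.594 without lung tumor 2.

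**Figure D2:**
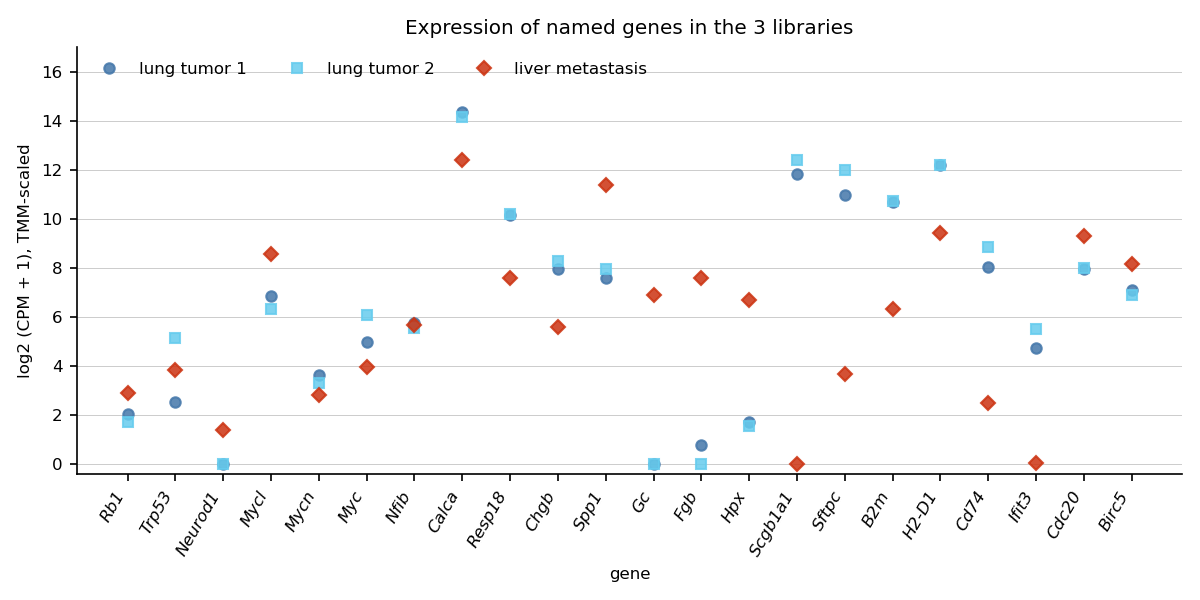
Points are log2(CPM + 1) of named genes in lung tumor 1 (circles), lung tumor 2 (squares) and the liver metastasis (diamonds), 1 library each, so no error bars are drawn. Mycl, Neurod1, Spp1, Gc, Fgb, Hpx, Cdc20 and Birc5 lie above both lung tumors in the metastasis, and Myc, Calca, Resp18, Chgb, Scgb1a1, Sftpc, B2m, H2-D1, Cd74 and Ifit3 lie below both.

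The non-neuroendocrine list was lower (6 of 16 members fell and 0 rose; 9 fell over the list alone; camera adjusted p = 0.0137, and 0.702 with an estimated correlation; median -1.42). Anxa1 fell 9.24-fold and the YAP partner Wwtr1 fell 5.59-fold. The median of the list also differed between the lung tumors (log2 lung 1 over lung 2 of -0.65), as did those of the alveolar, airway and fibroblast lists (-0.67, -0.61 and -0.52). On the log2 CPM scale the median of the non-neuroendocrine list was -1.34, with -1.82 without lung tumor 1 and -0.817 without lung tumor 2. In the tuft-cell list Sox9 and Dclk1 rose, Avil and Ptgs1 fell and 5 of 9 did not pass; the counts were the same over the list alone and the list did not shift (camera adjusted p = 0.251).

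Genes of plasma proteins that hepatocytes secrete were among the most raised in the metastasis, beside others such as Tm4sf4 and Hsd17b13, which do not encode plasma proteins. Gc (ENSMUSG00000035540, chromosome 5, 89417522 to 89457898), the vitamin D binding protein, had 0 counts in both lung tumors and 117 CPM in the metastasis, at least 1895-fold higher (edgeR adjusted p = 1.22e-05). Tm4sf4 was at least 1165-fold, Serpina1c at least 793-fold, Hsd17b13 at least 639.5-fold, Serpina1a at least 549.7-fold and F12 at least 296-fold higher, each with 0 counts in both lung tumors. Fgb, the fibrinogen beta chain, was 545-fold higher at 192 CPM, Serpina1b 427-fold, Ambp 253-fold, Apoh 101.5-fold, H2-Q10 84.8-fold and the heme carrier Hpx 48.3-fold. The Serpina1 genes and H2-Q10 belong to families of near-identical copies, so the split of reads among them is uncertain. Of 27 hepatocyte genes tested, 12 rose and 0 fell (13 rose over the list alone; camera adjusted p = 2.09e-07, median 2.65), with an adjusted p of 0.618 with an estimated correlation. Alb, chosen after its values were seen, reached 16.4 CPM in the metastasis, below Fgb and Gc. Hp, at 355 and 542 CPM against 343 CPM, and Trf, at 83.4 and 199 CPM against 223 CPM, did not pass. Of the raised genes named here, Hpx kept its call with limma voom (adjusted p = 0.0236), and Gc, Tm4sf4, Fgb, Hsd17b13, F12, Ambp, Apoh, H2-Q10, Alb and the Serpina1 genes did not. All lung reads of Fgb (34 counts) and of Alb (42 counts) came from lung tumor 1. All lung reads of Serpina1b (14 counts), Ambp (23 counts) and Apoh (25 counts) did as well, and H2-Q10 had 24 and 5 counts in lung tumors 1 and 2. The folds of these genes thus rest on few reads. With both lung tumors the log2 fold change of Alb was 5.24. Without lung tumor 1, Alb, Fgb, Serpina1b, Ambp and Apoh are at 0 in the lung tumor that remains. Only a lower bound would be possible for them, and no value is given. The log2 difference of H2-Q10 was 7.52 without lung tumor 1. Without lung tumor 2 the log2 differences were 8.01 (Fgb), 7.55 (Serpina1b), 6.87 (Ambp), 5.56 (Apoh) and 5.55 (H2-Q10).

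Among bile duct genes, Spp1 (osteopontin) rose 12.2-fold, from 217 ± 39.7 CPM (SD, n = 2) to 2652 CPM (log2 fold change 3.61, SE 0.24, edgeR adjusted p = 3.61e-05). Krt19 and Tspan8 fell, and 6 of 9 members of the cholangiocyte list did not pass, among them Krt7 at 3327 and 2532 CPM against 2281 CPM. Over the list alone 2 rose and 2 fell. The list did not shift (camera adjusted p = 0.984), and its median of -0.36 and mean of 0.73 differed in sign. On the log2 CPM scale its median was -0.347, with -0.15 without lung tumor 1 and -0.53 without lung tumor 2.

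Lung epithelial genes were far lower in the metastasis. Scgb1a1 (ENSMUSG00000024653, chromosome 19, 9083636 to 9087958), the club cell secretoglobin, stood at 3616 and 5326 CPM in the lung tumors and had 0 counts in the metastasis, at least 67700-fold lower (edgeR adjusted p = 3.22e-06; 0.263 with limma voom). Scgb3a1 was 2295-fold, Scgb3a2 129-fold, Cbr2 707-fold and Bpifb1 501-fold lower. The surfactant genes Sftpc and Sftpd were 256-fold and 288-fold lower, and Sftpa1 stood at 216 and 526 CPM in the lung tumors and had 0 counts in the metastasis. Chil1, Srxn1 and Retnla were also among the 12 genes furthest below, at 363-fold, 86.8-fold and at least 1226-fold. Without lung tumor 2 the log2 differences of Sftpc and Chil1 were -7.39 and -7.77, and without lung tumor 1 they were -8.42 and -8.87. In the alveolar list 13 of 17 members fell and 0 rose (camera adjusted p = 4.23e-08, and 0.618 with an estimated correlation); over the list alone 15 fell and 1 rose. In the airway list 8 of 12 fell and 0 rose (9 fell over the list alone; camera adjusted p = 1.22e-06, and 0.618 with an estimated correlation). The list medians were -6.00 and -5.38, or -5.00 and -3.92 with genes at 0 set to their bounds. Both lists were also lower in lung tumor 1 than in lung tumor 2, with medians of -0.67 and -0.61. Mesothelial genes were lower too: Msln, Upk3b, Lrrn4 and Krt19 fell among 8 (6 over the list alone; camera adjusted p = 0.00156, and 0.618 with an estimated correlation; median -3.48, or -3.18 with bounds).

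Stromal and blood vessel genes were lower in the metastasis. Of 19 fibroblast, stellate and pericyte genes, 13 fell and 0 rose (14 over the list alone; camera adjusted p = 0.000111, and 0.618 with an estimated correlation; median -2.59, or -2.54 with bounds); the matrix proteoglycan Dcn fell 17.6-fold and Mgp 93.1-fold. Of 18 genes of epithelial-mesenchymal transition and matrix remodelling, 7 fell and 0 rose (10 over the list alone; camera adjusted p = 0.00018, and 0.618 with an estimated correlation; median -1.75), with Sparc 6.99-fold and Mmp14 5.40-fold lower. Of 14 endothelial genes, 6 fell and 0 rose (8 over the list alone; camera adjusted p = 0.00523, and 0.618 with an estimated correlation; median -1.94); Plvap fell 13.0-fold and Emcn was at least 24.8-fold lower. The fibroblast and matrix lists differed between the lung tumors (medians of -0.52 and -0.63), the endothelial list by 0.03. None of 8 liver sinusoidal endothelial genes passed, over all genes or over the list alone (camera adjusted p = 0.191, median -2.07), and the sinusoidal receptor Stab2 stood at 2.31 and 1.26 CPM in the lung tumors and 2.16 CPM in the metastasis. The sinusoidal median on the log2 CPM scale went from -1.82 to -1.09 without lung tumor 2 and to -1.04 with no filter.

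Immune cell genes were lower in the metastasis for some cell types. Of 15 macrophage genes, 5 fell, among them Cd68, C1qb, C1qc and Trem2, and 0 rose (8 fell over the list alone; camera adjusted p = 0.0178, and 0.618 with an estimated correlation; median -1.32); Cd68 fell 3.08-fold, and Trem2 fell from 5.56 and 2.76 CPM to 0.264 CPM. The macrophage median on the log2 CPM scale went from -1.09 to -1.68 without lung tumor 2. Of 8 T and NK cell genes, Gzma (at least 70.2-fold) and Trbc2 (at least 22.0-fold) fell, and 3 fell over the list alone. The list was lower (camera adjusted p = 0.0471, and 0.618 with an estimated correlation), with a median of -4.17, or -1.82 with bounds. Its call ended with library totals (camera adjusted p = 0.0835), where the median on the log2 CPM scale went from -1.62 to -1.79. With no filter the call ended too (camera adjusted p = 0.292), and that median shrank to -0.759. Of 10 B and plasma cell genes, Cd79a, Igkc and Igha fell (4 over the list alone; camera adjusted p = 0.134, median -1.06; adjusted p = 0.0457 with a mean count of at least 10); without lung tumor 1 the log2 differences of Igkc and Igha went from -2.64 and -2.69 to -1.57 and -1.74. No gene of the neutrophil list (11 tested, camera adjusted p = 0.161, median -0.93), the platelet list (7 tested, adjusted p = 0.261, median -1.32) or the erythroid list (6 tested, adjusted p = 0.233, median -0.76) passed, over all genes or over the list alone. Lcn2 stood at 112 and 204 CPM against 107 CPM, Itgb3 at 8.51 and 5.30 CPM against 2.77 CPM, and Hba-a1 at 22.1 and 40.2 CPM against 20.6 CPM. On the log2 CPM scale the erythroid median of -0.716 was -1.1 without lung tumor 1 and -0.264 without lung tumor 2, and the B and plasma cell median of -0.997 was -0.646 without lung tumor 2.

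Antigen presentation and interferon genes were lower in the metastasis. B2m (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), the light chain of MHC class I, fell 20.9-fold from 1668 ± 19.7 CPM (SD, n = 2) to 79.8 CPM (log2 fold change -4.39, SE 0.28, edgeR adjusted p = 2.9e-05). The heavy chain gene H2-D1 fell 6.73-fold and the immunoproteasome gene Psmb8 19.9-fold. Of 13 MHC class I presentation genes, 10 fell and 0 rose (12 over the list alone; camera adjusted p = 8.24e-07, and 0.618 with an estimated correlation; median -3.00). Of 8 MHC class II genes, 7 fell and 0 rose, over all genes and over the list alone (camera adjusted p = 2e-05, and 0.618 with an estimated correlation; median -5.29), with Cd74 77.6-fold and H2-Ab1 40.6-fold lower. Of 21 interferon response genes, 15 fell and 0 rose (18 over the list alone; camera adjusted p = 3.67e-08, and 0.618 with an estimated correlation; median -3.15); Usp18 fell 8.86-fold, Cxcl10 5.13-fold and Ifit3 801-fold, from 25.4 and 45.1 CPM to 0.044 CPM, which is 2 counts; limma voom did not keep the call of Ifit3 (adjusted p = 0.471). The class II and interferon lists were also lower in lung tumor 1 than in lung tumor 2 (medians of -0.61 and -0.49), as the lung epithelial lists were, and the class I list by a median of -0.12.

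Some cell division and respiration genes were higher in the metastasis. Of 25 cell cycle genes, Cdc20 (2.54-fold), Birc5 (2.24-fold), Top2a, Cenpa and Ube2c rose and 0 fell, over all genes and over the list alone (camera adjusted p = 0.0131, and 0.618 with an estimated correlation; median 0.48), while Pcna stood at 693 and 597 CPM against 577 CPM. Of 20 oxidative phosphorylation genes, Atp5o (2.103-fold), Ndufb8 (2.06-fold) and Cox6c rose and 0 fell, over all genes and over the list alone (camera adjusted p = 0.0197, and 0.618 with an estimated correlation; median 0.42); Cox4i1, at 1802 and 982 CPM against 2784 CPM, did not pass. The call of the latter list ended with library totals (camera adjusted p = 0.0756). Among random lists matched on expression, its median lay at percentile 86.8, and that of the cell cycle list at 99.25. Between the lung tumors the oxidative phosphorylation list differed by a median of 0.19 (percentile 89.87), so its shift in the metastasis is not set apart from that spread. The cell cycle list differed there by -0.03. On the log2 CPM scale the cell cycle median went from 0.49 to 0.323 without lung tumor 1 and 0.211 with library totals, and the oxidative phosphorylation median from 0.436 to 0.281 without lung tumor 2. The 13 mitochondrial protein-coding genes were higher in the metastasis by a median log2 difference of 1.25.

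Genes that respond to handling of tissue were lower in the metastasis. Of 19 immediate early and heat shock genes, 12 fell and 0 rose (14 over the list alone; camera adjusted p = 4.8e-05, median -1.12), with Hspa1a 8.96-fold and Hspa1b 5.52-fold lower and Egr1 at 3784 and 2862 CPM against 2063 CPM, which did not pass over all genes. The adjusted p with an estimated correlation was 0.618. This list differed by a median of -0.05 between the lung tumors.

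The other lists did not shift under the main settings. With library totals the epithelial adhesion list (adjusted p = 0.0433), the unfolded protein response (adjusted p = 0.0433) and the p53 targets (adjusted p = 0.0374) passed as lower, and with no filter epithelial adhesion (adjusted p = 0.049) and the p53 targets (adjusted p = 0.0322) did. In epithelial adhesion, Cldn4 (34.3-fold), Krt8 (1.87-fold), Krt18 (2.47-fold) and Krt19 (5.46-fold) fell among 14, also over the list alone (camera adjusted p = 0.107, median -0.29). In the list of genes tied to metastasis in SCLC models, Mycl and Bcl2 rose and Nfix and Gadd45g fell among 14 (3 rose and 3 fell over the list alone; camera adjusted p = 0.734, median -0.20), and Ptn stood at 224 and 224 CPM against 314 CPM. In hypoxia, Pdk1 rose and Car9 and P4ha2 fell among 18, also over the list alone (adjusted p = 0.669, median -0.04). In the unfolded protein response, Atf3, Xbp1 and Dnajb9 fell among 16, also over the list alone (adjusted p = 0.136, median -0.25). Among 18 p53 targets, Cdkn1a and Ccng1 fell (1 rose and 5 fell over the list alone; adjusted p = 0.0578, median -0.67), and Bax stood at 244 and 238 CPM against 419 CPM. Among 12 Wnt targets, Ccnd1 rose and Myc fell, also over the list alone (adjusted p = 0.347, median 0.15, mean -0.69, and median -0.01 with library totals). No gene passed, over all genes or over the list alone, among 20 of the Notch pathway (adjusted p = 0.218, median -0.35; Hes1 at 86.2 and 115 CPM against 61.7 CPM) and 19 of cholesterol synthesis (adjusted p = 0.942, median 0.02, mean -0.05, and median -0.26 with library totals; Pmvk at 172 and 167 CPM against 143 CPM). Without lung tumor 1 and without lung tumor 2, in this order, the medians on the log2 CPM scale were 0.0381 and 0.603 for the Wnt targets (0.263 with both), -0.146 and -0.435 for epithelial adhesion (-0.265 with both), -0.0927 and -0.107 for hypoxia (-0.0396 with both), and 0.00389 and -0.0362 for cholesterol synthesis (0.0224 with both).

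**Figure D3:**
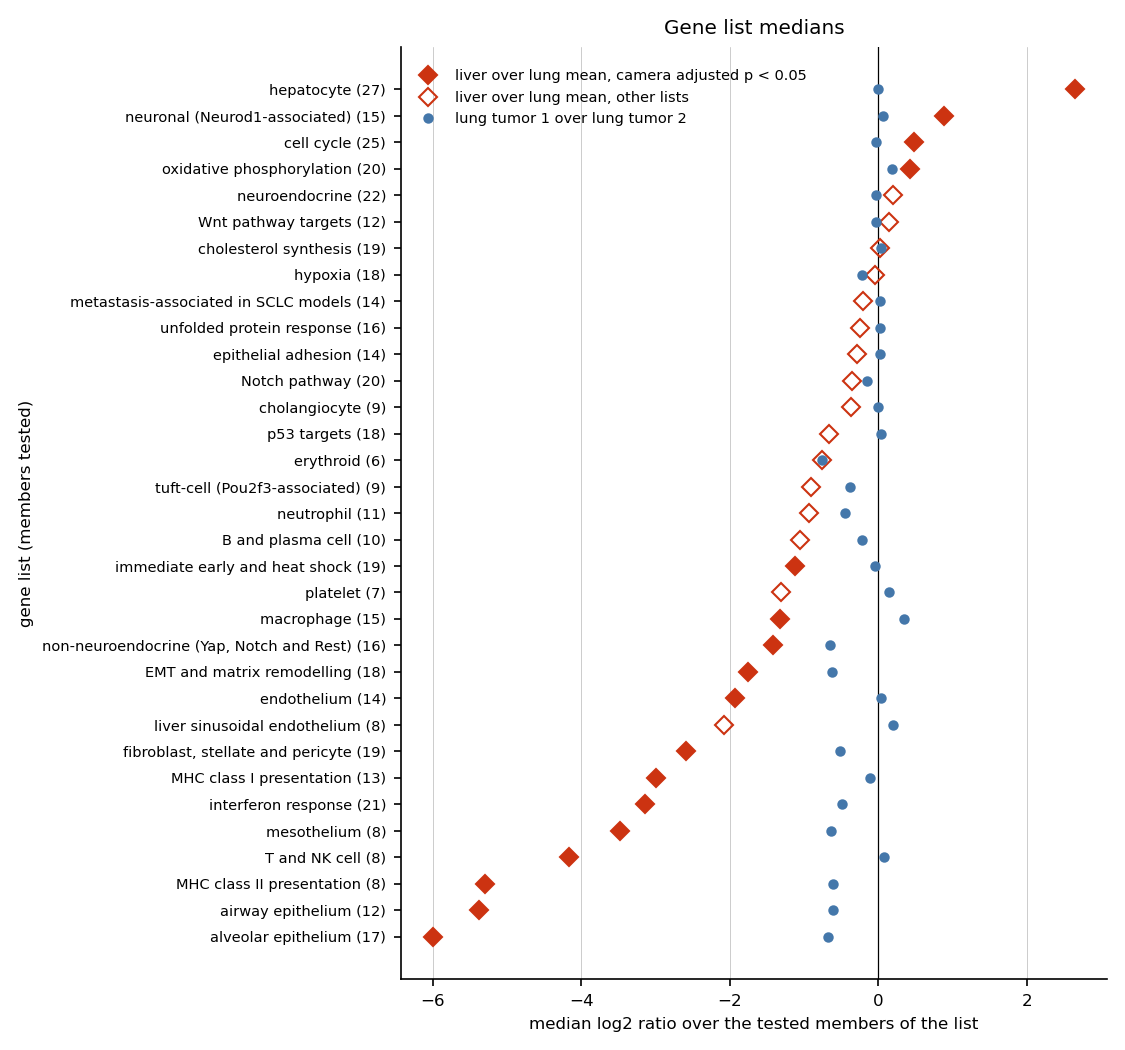
Diamonds are the median log2 fold change of each of the 33 gene lists, liver metastasis over lung tumors, filled where camera's adjusted p was under 0.05; circles are the median log2 ratio of lung tumor 1 over lung tumor 2 for the same genes. Filled diamonds lie above 0 for 4 lists and below 0 for 13, from 2.65 (hepatocyte) to -6.00 (alveolar epithelium); none of these calls held with an estimated correlation.

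Across the lists, 4 shifted higher and 13 lower by camera with a preset correlation, 0 with an estimated correlation, and 0 by fry after adjustment (smallest adjusted p 0.117). The estimated correlation and fry rest on 1 residual degree of freedom.

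The question of setting the lung tumors side by side was how far nodules of the same site differ. Of 11216 genes with a mean of at least 5 CPM in the lung tumors, 19 lay at least 4-fold higher and 29 at least 4-fold lower in lung tumor 1 than in lung tumor 2, which has no replicate check. The largest differences were Commd1b (63.2 against 0 CPM), Msl3l2 (34.8 against 0.67 CPM), Rpl29 (140 against 6.37 CPM), H2bc6 (27.7 against 0.555 CPM) and Rn7s6 (10.8 against 0 CPM) in lung tumor 1, and Exosc6 (0.744 against 51.9 CPM), Raver1 (0 against 25.1 CPM), B3gnt2 (3.47 against 61.9 CPM), Nup62 (23.5 against 188 CPM) and Bola1 (14.1 against 103 CPM) in lung tumor 2. The gene model of 32 of these 48 genes (66.7%) overlapped another listed gene, against 43.3% of the 11168 other genes (Fisher's exact test, two-sided, p = 0.00123), and H2bc6 is one of many histone copies, so these values are uncertain. Commd1b and B3gnt2 overlap each other on chromosome 11 and went opposite ways between the lung tumors, so they may not be separate differences. Across genes, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.964 between the lung tumors and 0.87 and 0.834 between the metastasis and lung tumors 1 and 2.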

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

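The fit without mitochondrial genes was chosen after seeing the data. For the liver metastasis against the lung tumors, the count of 2372 genes stayed within 1.5 times with DESeq2, DESeq2 size factors, upper quartile scaling, TMM without listed genes, library totals, no filter, a mean count of at least 10, predicted genes left out and mitochondrial genes left out (1693 to 2812 genes). limma voom called 277 genes (143 higher, 134 lower), the test against a 2-fold change 961 (198 and 763), limma-trend on FPKM 1057 (261 and 796), with a pseudocount of 0.1 1225 (245 and 980), and with no filter 0 (0 and 0, with 5261 at an unadjusted p under 0.05). Library totals called 532 genes higher in place of 891. By size, the counts above and below the lung tumors were 581 and 987 with a 2-fold limit, 23 and 132 with an 8-fold limit, and 37 and 183 with a mean of at least 20 CPM. The count above was 127 with a mean of at least 1 CPM and 54 with library totals. Leaving out each lung tumor gave 121 to 176 above and 353 to 476 below. For lung tumor 1 against lung tumor 2, a 2-fold limit gave 121 above and 190 below, an 8-fold limit 8 and 10, a mean of at least 20 CPM 8 and 12, and FPKM values 41 and 45, and a mean of at least 1 CPM gave 37 above. Fewer genes pass a higher limit by construction; for the other settings the cause was not tested. Of the gene lists, 0 shifted higher and 0 lower with an estimated correlation, and 0 and 0 by fry. The direction of the list test turned, with no call and with the sign of the median kept, for the cholangiocyte list with no filter (median -0.436, adjusted p = 0.787) and for cholesterol synthesis by fry (median 0.0224, adjusted p = 0.414) and with no filter (median 0.0199). The median itself turned for cholesterol synthesis with library totals (-0.256) and without lung tumor 2 (-0.0362), and with library totals for the neuroendocrine list (0.197 to -0.0824) and the Wnt targets (0.263 to -0.0123). Signs of genes that did not pass turned for Stab2 without lung tumor 2 (-0.0996), Trp53 with limma voom (0.0327) and without lung tumor 2 (1.47), and Nfib with library totals (-0.264), without lung tumor 2 (-0.0912) and on FPKM (-0.21, -0.274 and -0.21); the cause was not tested. Of 121 named genes, of which 98 passed the main test, 66 were no longer past the threshold with limma voom, 98 with unfiltered FPKM, 23 with filtered FPKM, 19 with a pseudocount of 0.1, 36 with the test against a 2-fold change, 22 with no filter, 10 with library totals, 8 with DESeq2, 7 with a mean count of at least 10, 2 with upper quartile scaling and 1 with predicted genes left out. Leaving out a lung tumor leaves 1 library on each side, which gives values and no test, so no count of calls was made; 17 of these genes moved by more than the spread of the lung tumors without replicate 1 and 21 without replicate 2. Simulated counts at this depth and design recovered 7 of 100 genes changed 2-fold, so changes of this size can be missed. The simulation gave each gene the spread typical of its expression level and led to 104 calls, against 2372 in the real data. In the real data some genes near 2-fold passed, such as Ndufb8 (2.06-fold), and others did not, such as Cox4i1 (2-fold). The share missed in the real data is thus not known.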

Other observations

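The KEGG tests below, and the tests of chance order, of runs with few genes of a gene family, of lung epithelium and of hepatocytes, were chosen after the results were seen. Those of GC content, of genes left out of the scan and of the left-out genes of chromosome 19 were set before their results were seen.

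Ribosomal genes had the smallest p among 304 KEGG pathways tested: 51 of 132 rose and 0 fell (camera adjusted p = 2.42e-10, and 0.835 with an estimated correlation; median log2 fold change 0.72). In oxidative phosphorylation 40 of 129 genes rose and 2 fell (adjusted p = 1.9e-05, and 0.835 with an estimated correlation), and in the spliceosome 11 of 130 rose and 2 fell (adjusted p = 0.00247, and 0.835 with an estimated correlation). Lysosomal genes went the other way, with 29 of 121 fallen and 1 risen (adjusted p = 9.73e-06, and 0.835 with an estimated correlation), as did drug metabolism by cytochrome P450, with 17 of 46 fallen and 0 risen (adjusted p = 0.0157, and 0.835 with an estimated correlation). Immune pathways had smaller p among the lower ones, such as antigen processing and presentation (30 of 62 fallen and 2 risen, adjusted p = 2.28e-08, and 0.835 with an estimated correlation) and cytokine receptor interaction (37 of 179 fallen and 2 risen, adjusted p = 8.7e-08, and 0.835 with an estimated correlation). Of the 240 pathways left after most of those named for diseases were set aside, 6 shifted higher and 36 lower, and those not named here are not described.

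Some genes that shifted in the metastasis lay in runs along chromosomes: a scan of 10274 protein-coding genes in windows of 31 neighbors found 6 runs higher and 6 lower than the limit that 5% of 1000 shuffles pass (0.66 on the log2 scale), and 1 run between the lung tumors past a limit of their own (0.35); on chromosome 4, 62 genes from 124714776 to 129672767 had a median shift of 0.66 and 41 genes from 154011731 to 156247616 one of -0.75, and on chromosome 1, 56 genes from 171329145 to 182517524 had 0.73 and 56 from 180976210 to 195131561 had -0.79. The higher and the lower run of chromosome 1 overlap from 180976210 to 182517524, since windows were joined by direction. Genes there belong to both runs, and the edges of runs are uncertain. For the largest window chance order is argued against, since 0 of 1000 shuffles gave one as large as 1.06. The limit came from the same shuffles, so this adds little for the other runs. The largest shuffled window was 0.944, and most runs peaked below it, down to 0.66 for the run of chromosome 19. A trend on GC content, length or level as the whole cause is argued against, since 10 of the 12 runs stayed past the limit without it. A change of whole stretches, such as copy number, may account for part of this: 68 of 105 weakly expressed genes kept out of the scan went the way of their run (median 0.36, permutation p = 0.0007, one-sided), and 45 of 75 did in the 9 runs that hold fewer than 4 histone, Cyp2 or H2 genes (median 0.28, bootstrap 95% interval -0.13 to 0.46, p = 0.021), but by single runs they went both ways, with a median of -0.24 in the higher run of chromosome 1, -0.28 and 0.002 in higher runs of chromosome 4 and 0.57 in the lower run of chromosome 8. Over the whole of chromosome 19 the 356 scanned genes were higher by a median of 0.38. Of these, 250 lay above the median of all scanned genes. Against random sets of scanned genes, the permutation p adjusted over the chromosomes was 0.002. Chromosomes 2, 4, 8 and 11 passed too, with smaller medians (-0.06, 0.08, 0.10 and -0.09). Between the lung tumors the shift of chromosome 19 was -0.035. Its left-out genes were higher by 0.17 (95% interval 0.005 to 0.388, permutation p = 0.069, one-sided), which missed the threshold set beforehand. A missed threshold was a poor bound, since the interval also reaches the shift of the scanned genes. The left-out genes thus do not tell a change of the whole chromosome, such as copy number, apart from none. The permutation p-values here come from genes drawn singly, as if neighbors were independent, and may be too small. Left-out genes that overlap a scanned gene were not removed and may carry its reads. DNA was not analysed here, and regional regulation stays open.

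Lower antigen presentation and interferon genes in the metastasis could come from lung epithelium carried along in the lung nodules. Lung epithelial markers differed between the lung tumors by a median log2 ratio of -0.68 (95% bootstrap interval -0.75 to -0.56, 24 genes), and the class II genes followed them (-0.57, 7 genes, difference 0.11, interval -0.20 to 0.20). The class I genes did not, with -0.12 over 12 genes (difference 0.56, interval 0.43 to 0.70), and the interferon genes lay apart by 0.19 with an interval (0.008 to 0.62) that nearly reaches 0. These intervals are over genes of 1 library each. The macrophage list went the other way between the lung tumors (median 0.34). Opposite differences of 2 cell sources could cancel, so the class I values do not exclude a part from lung epithelium. Other cells of the lung nodules, and lower expression in the tumor cells of the metastasis, stay open and were not tested.

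Plasma protein genes in the liver metastasis may be thought to come from hepatocytes carried along. Albumin mRNA is among the most abundant in hepatocytes, yet Alb had 743 counts against 8702 for Fgb and 5337 for Gc. The ratios were 0.0854 (exact 95% interval 0.0791 to 0.092) and 0.139 (0.129 to 0.15), with intervals over counts only. This argues against hepatocytes with more Alb than Fgb or Gc mRNA as the source of most Fgb and Gc. No liver tissue without tumor was measured, so the ratios in hepatocytes of this mouse are not known. Hepatocytes with less Alb mRNA stay open as a source. A smaller share of hepatocytes, enough for the Alb reads, stays open. Whether tumor cells in the liver express Fgb and Gc was not tested.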
